A study of Mus musculus with 2 samples.

How the data were processed

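Polyadenylated RNA of mouse neural tube at embryonic day 12.5 was measured in 2 libraries, each made from a separate pool of embryos of both sexes. Per the labels, replicate 1 came from 120 embryos and replicate 2 from 88 embryos of strain B6NCrl. Each library started from 10 ng of total RNA, was primed with oligo-dT with a kit for very low input, fragmented by tagmentation and given ERCC spike-ins, which are synthetic RNAs of known identity. The labels name no strand-specific step, so reads of a gene and of its antisense partner cannot be told apart here.

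The authors deposited 2 gene tables and 2 transcript tables per library. Per the notes deposited with each library, reads were aligned to the transcriptome on assembly mm10 and quantified once against GENCODE release M21 and once against release M4. The aligner, the quantifier and their versions are not given in the sources used here; per the file headers, the column names are those that RSEM writes. The deposited estimated count is the number of reads assigned to a gene, with reads that match several genes shared out among them, and it need not be whole. The deposited TPM (a transcript abundance unit) is that estimate divided by effective length and scaled to the same fixed sum in each library over the whole table, spike-ins and tRNAs included. Per the file headers, each transcript's percent of its gene's TPM is deposited in the transcript tables, and a posterior standard deviation of each count is given in all tables. Because shared reads are divided by an estimate, pseudogenes and near-identical paralogs carry an uncertain count, which is stated where such a gene is named.

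Before the data were examined, the sample groups, the tests, the rule for naming genes, 38 gene lists with 451 genes and the alternatives were fixed. The M21 gene tables were the main source by a rule fixed then (the newer release). All 55536 gene IDs of the M21 tables were named from the GENCODE M21 annotation, and 42462 of the 43346 gene IDs of the M4 tables were named by ID without version. Of the listed genes, 450 were measured; Ahsp was not measured, and Drgx was found as Prrxl1.

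Levels are TPM as deposited, given as mean ± SD over the 2 libraries. A gene was counted as expressed at a TPM of at least 1 in both. Ratios between genes or gene groups within a library are log2 ratios of TPM, with no pseudocount. With 1 group there is no comparison between conditions, so the libraries were compared with each other, and the outcome describes these 2 libraries only, with no replicate check. For that comparison the estimated counts were rounded to whole numbers, library sizes were scaled by TMM in edgeR 4.0.16 under R 4.3.3, and genes with at least 10 counts in either library were kept. The log2 ratio of replicate 2 over replicate 1 was computed with a prior count of 2. A two-sided exact binomial test of the 2 counts against the scaled library sizes gave a p-value per gene, adjusted by Benjamini-Hochberg at 0.05. That test covers counting error only, and without molecular identifiers PCR copies count as separate reads. The biological coefficient of variation came from edgeR's common dispersion in an intercept-only model. For each of 37 lists (all but the isoform list) the median log2 ratio was set against 10000 random lists of the same size, each member replaced by a gene within 100 ranks of its mean expression. A list outside the central 95% of these medians is called higher or lower. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

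Genes are named by this rule. Named are the 20 nuclear protein-coding genes with the highest mean TPM; up to 6 highest and 3 lowest members of each list, with all members of the Hox, sex-linked and transmitter lists; and the genes in the ratios. Also named are the 10 genes with the largest log2 ratio between libraries in each direction, at a mean TPM of at least 10 and an adjusted p under 0.05; the isoform list; and the 10 genes that differed most between annotation releases. Any gene outside this rule is said to be chosen later, and some genes under it are left out of the text.

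The total was 33529531 estimated counts in replicate 1 and 35461403 in replicate 2. A read in a transcript of 1 kb effective length was worth 0.0477 TPM in replicate 1 and 0.0462 TPM in replicate 2. A count of 0 allows up to 3 counts, or 0.143 and 0.138 TPM at that length; limits and intervals cover counting error only. The binomial test was tested on simulated data for 20125 genes, with 200 genes changed at each fold. It recovered 48.5% of genes changed 1.25-fold, 67.0% of those changed 1.5-fold and 77.0% of those changed 2-fold. Of 300 simulated lists of 12 unchanged genes 5.33% fell outside the central 95%. The simulated counts held counting (Poisson) error only, and the simulated list ratios independent normal noise, equal at all expression levels. The real libraries differed by more than counting error (chi-square of 6.998 per degree of freedom), so these rates do not calibrate the tests on them. Alternatives were other TPM thresholds, the M4 tables, TPM rescaled without mitochondrial genes and spike-ins, posterior mean TPM, CPM without length correction, another pseudocount and other count filters. DESeq2 1.42.0 size factors, ERCC scaling, TPM as the scale, edgeR's exact test at the common dispersion and each library alone were also tried. With TPM as the scale the log2 ratio was that of TPM + 1, so a pseudocount of 1 TPM replaced the prior count of 2. A change under that alternative cannot be put down to the scale alone. Removing a linear trend on transcript length and GC content, and leaving out 1 list member, a result not reported here, were chosen after seeing the data.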

Results

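The series profiled the neural tube of mouse embryos at embryonic day 12.5, when the spinal cord holds dividing progenitors beside newly born neurons. It has 1 group of 2 biological replicates, a pool of 120 embryos (replicate 1) and a pool of 88 embryos (replicate 2). The labels state no question beyond profiling the polyadenylated RNA of this tissue. Replicate 1 held 33529531 estimated counts and replicate 2 held 35461403. Genes took 97.1% ± 0.0688 of them (SD, n = 2) and ERCC spike-ins 2.94% ± 0.0688. Of the counts on genes, 94.98% ± 0.383 fell on protein-coding genes and 1.07% ± 0.0536 on mitochondrial genes. All levels that follow are TPM, mean ± SD over the 2 libraries (n = 2).

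Among nuclear protein-coding genes the highest was Actb, which encodes cytoplasmic actin, at 11160 ± 1025 TPM, before Tuba1a, the alpha tubulin of growing neurons, at 8445 ± 6.20 TPM. The embryonic globin Hbb-y followed at 5367 ± 81.6 TPM, then the actin-binding Tmsb4x at 5168 ± 564 TPM, the ferritin light chain gene Ftl1 at 4660 ± 181 TPM and Tmsb10 at 4417 ± 223 TPM. Stmn1, a tubulin-binding phosphoprotein of dividing and immature neural cells, reached 3885 ± 76.7 TPM, and the imprinted gene Nnat 2621 ± 106 TPM. The other members of the top 20 were Hba-a2, Ppia, Ubb, Actg1, Hist1h2ap, H3f3a, Cfl1, Eef1a1, Ptma, Hspa8, Rpl41 and Hba-a1. At a TPM of at least 1, 15843 genes were expressed in both libraries, with 751 more in replicate 1 alone and 624 more in replicate 2 alone. They included 13414 of 22028 protein-coding genes (60.9%), 540 processed pseudogenes and 383 lincRNAs. A TPM of at least 100 in both was reached by 1609 protein-coding genes.

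The pan-neuronal list had a higher median than the neural progenitor list, though their ranges overlapped. All 17 pan-neuronal genes were at 10 TPM or more in both libraries, with a median of 276 ± 5.37 TPM. Among them were Tubb3 (neuronal beta tubulin, 967 ± 20.3), the neurofilament gene Nefl (626 ± 80.4), Uchl1 (574 ± 41.2), Ina (500.2 ± 8.17) and Stmn2 (487 ± 78.1); the lowest was the synaptic vesicle gene Syt1 at 34.0 ± 2.05 TPM. All 14 neural progenitor genes were expressed, with a median of 47.2 ± 0.371 TPM, from Fabp7 (radial glial fatty acid binding protein, 1430 ± 49.3), Vim (904 ± 36.6) and the Notch effector Hes5 (317 ± 6.90) down to Sox1 (1.53 ± 0.0849). All 16 proliferation genes exceeded 10 TPM, with Cdk1 at 175 ± 1.81, Ccnb1 at 155 ± 0.750 and Top2a at 151 ± 1.41 TPM. All 12 genes of commitment to the neuronal fate were expressed, led by Hes6 (284 ± 3.48), Btg2 (92.3 ± 3.90) and the Notch ligand gene Dll3 (63.9 ± 1.31). On the log2 scale Tubb3 exceeded Sox2, a progenitor transcription factor, by 4.66 ± 0.06, while Fabp7 stood above Tubb3.

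**Figure D1:**
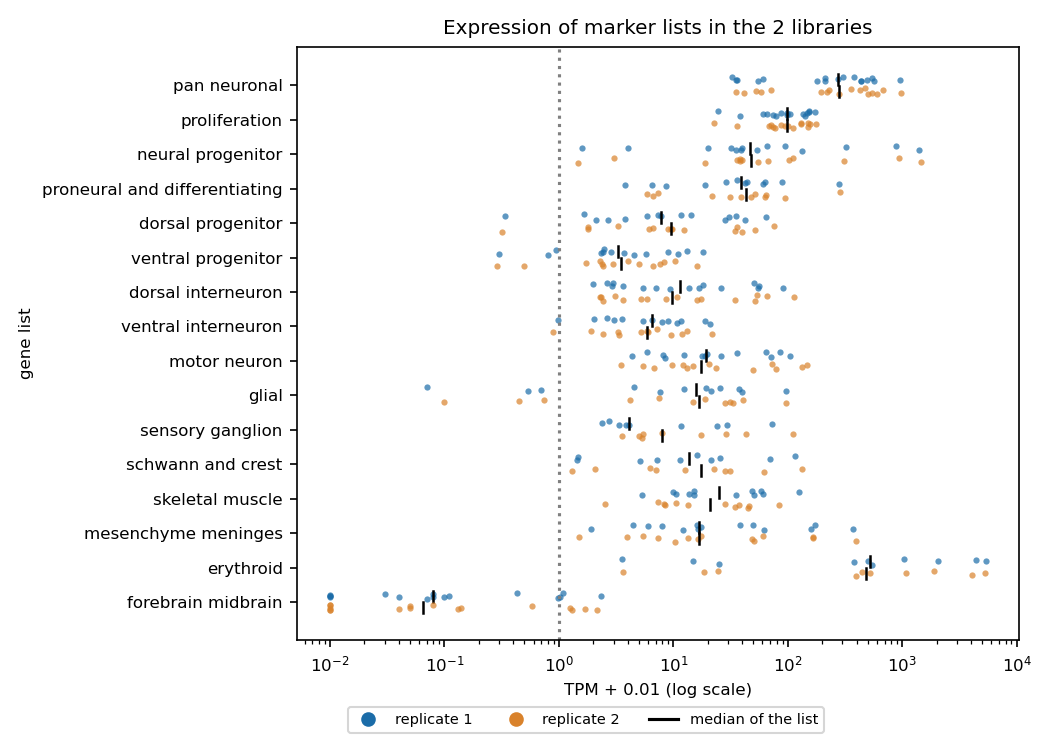
TPM of each member of 16 gene lists in replicate 1 (blue) and replicate 2 (orange) on a log axis, after adding 0.01; black bars are list medians and the dotted line marks a TPM of 1. Pan-neuronal genes had a median of 276 TPM and forebrain and midbrain genes lay near 0.

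Both dorsal and ventral identities were present, at lower levels. Of 15 dorsal progenitor genes 14 were expressed, the highest being Msx3 (69.7 ± 8.35), with Pax3 (35.4 ± 0.665) and the roof plate gene Msx1 (35.1 ± 6.73); the roof plate ligand gene Gdf7 stood at 0.320 ± 0.0141 TPM. Of 14 ventral progenitor genes 11 were expressed, led by Irx3 (17.2 ± 1.61), Dbx1 (11.8 ± 2.04), Nkx6-2 (9.58 ± 1.87) and Nkx6-1 (8.31 ± 0.983), while Foxn4 and Nkx2-9 were at 0.710 ± 0.311 and 0.285 ± 0.0071 TPM. Pax3 exceeded Nkx6-1 by 2.10 ± 0.20 on the log2 scale. All 16 dorsal interneuron genes were expressed, with Pou4f1 at 103 ± 16.6, Tlx3 at 58.2 ± 10.8, Lhx1 at 54.5 ± 0.742 and Lhx5 at 53.3 ± 3.01 TPM. Of 13 ventral interneuron genes 12 were expressed, with Foxp2 at 21.2 ± 0.474, Lhx3 at 16.1 ± 4.02 and Sox21 at 11.8 ± 0.134 TPM. All 14 motor neuron genes were expressed, led by Isl1 (127 ± 30.9), the peripherin gene Prph (109 ± 33.3) and Aldh1a2, a retinoic acid synthesis gene (75.2 ± 5.71); Chat, for acetylcholine synthesis, stood at 3.90 ± 0.636 TPM. Pou4f1, Tlx3, Isl1 and Prph are also known from sensory ganglia.

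Among transmitter genes, the vesicular glutamate transporter Slc17a6 stood at 40.3 ± 1.77 TPM, Slc17a7 at 1.82 ± 0.318 and Slc17a8 at 0.185 ± 0.0354 TPM. All 5 inhibitory genes were expressed, among them the GABA synthesis genes Gad2 (32.3 ± 4.73) and Gad1 (15.2 ± 2.39), the glycine transporter Slc6a5 (11.0 ± 0.474) and the vesicular transporter Slc32a1 (3.08 ± 0.460). Slc17a6 exceeded Slc32a1 by 3.72 ± 0.28 on the log2 scale. Of 8 monoamine genes 3 were expressed, Th (19.5 ± 3.66), Slc18a2 (8.14 ± 0.806) and Ddc (3.76 ± 0.127). Slc6a4, Dbh, Fev, Tph2 and Slc6a3 lay between 0.0900 and 0.545 TPM.

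Of 16 forebrain and midbrain genes, 2 passed the threshold in both libraries, Pitx3, a dopamine neuron gene (2.31 and 2.16 TPM in replicates 1 and 2), and Dlx2 (1.16 ± 0.127). Counting replicate 2 by itself 4 passed, with Emx2 at 1.69 TPM against 0.42 TPM in replicate 1. Nkx2-1 and Six6 were at 0 in both, which allows up to about 0.143 TPM for a transcript of 1 kb. In contrast, 36 of 39 Hox genes, which pattern the hindbrain and spinal cord along the body axis, were expressed. Hoxb6 (chromosome 11, 96292476 to 96301569, mm10) was the highest at 116 ± 3.61 TPM, before Hoxa9 (100.3 ± 4.24), Hoxb2 (89.3 ± 4.94) and Hoxa10 (89.3 ± 5.93). The median was 15.02 ± 1.52 TPM over paralog groups 1 to 4, 55.6 ± 2.40 over groups 5 to 8, 50.9 ± 3.11 for group 9 and 8.29 ± 3.57 over groups 10 to 13. Groups 5 to 8 exceeded groups 1 to 4 by 1.89 ± 0.21 and groups 10 to 13 by 2.81 ± 0.70 on the log2 scale, and group 9 exceeded groups 1 to 4 by 1.76 ± 0.06. Hoxa13, Hoxb13 and Hoxd13 were above 1 TPM in replicate 1 alone.

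**Figure D2:**
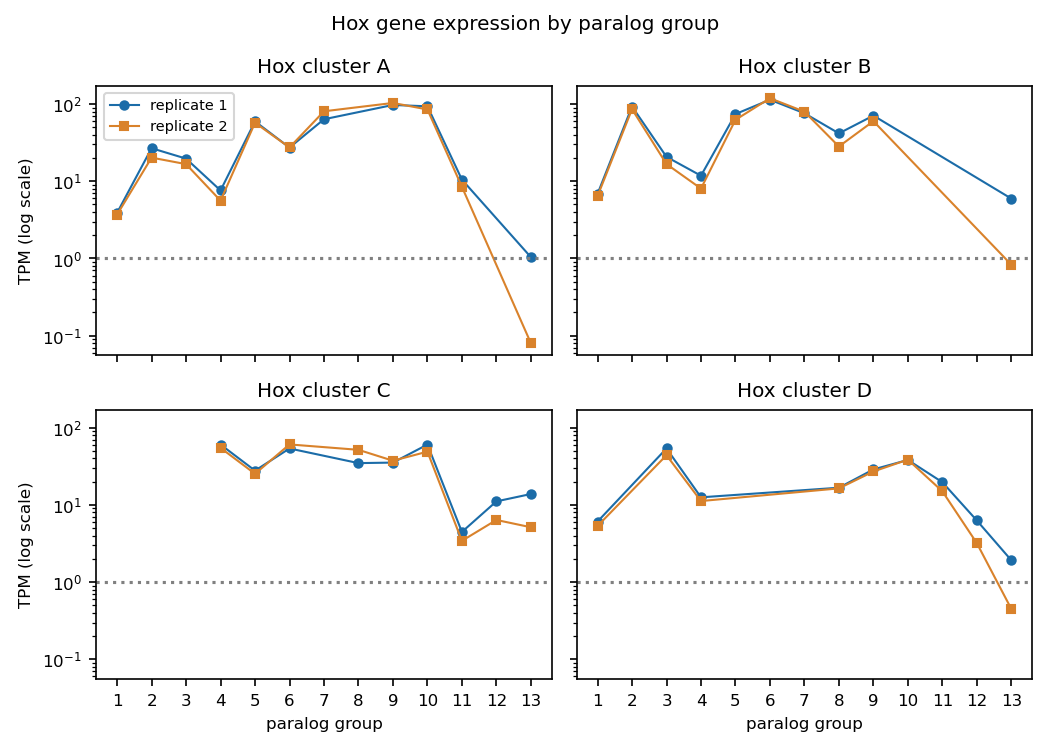
TPM (log axis) of the 39 Hox genes by paralog group in each cluster, replicate 1 as blue circles and replicate 2 as orange squares; the dotted line marks a TPM of 1. The libraries lie closer together in groups 1 to 11 than in group 13, where Hoxb13 was at 5.96 TPM in replicate 1 and 0.83 TPM in replicate 2.

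Genes of cells around the cord were measured as well. All 9 sensory ganglion genes were expressed, among them Prdm12 (36.0 ± 9.59). All 10 Schwann cell and crest genes were, led by Ednrb (125 ± 13.1) and Tfap2b (65.7 ± 5.24), and 2 of 5 sympathetic genes, Th and Phox2a (1.68 ± 0.255). All 14 mesenchyme and meninges genes (Col3a1, 382 ± 17.1), 9 of 10 cartilage and sclerotome genes (Col2a1, 147 ± 5.65) and all 12 skeletal muscle genes (Actc1, 104 ± 28.4; Acta1, 52.8 ± 11.8) passed the threshold. All 10 erythroid genes did too and took 0.462% ± 0.0186 of gene counts. Also expressed were all 10 endothelial genes (Cldn5, 44.0 ± 1.46), all 6 pericyte genes (Acta2, 41.4 ± 8.32), 11 of 12 macrophage and microglia genes (C1qb, 26.5 ± 1.41) and all 9 epidermal and epithelial genes (Krt5, at 10.1 and 10.8 TPM in replicates 1 and 2). Of the liver list 4 of 8 were expressed (Trf, 20.4 ± 0.566) and of the heart list 5 of 9 (Myh7, at 8.82 and 5.49 TPM). Of 12 glial genes 9 were expressed, with Sox9 at 96.4 ± 0.926 and Nfib at 40.2 ± 0.0778, whereas the astrocyte genes Aqp4 and Gfap were at 0.485 ± 0.0636 and 0.0750 ± 0.0212 TPM.

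Most signalling genes passed the threshold of 1 TPM. All 11 hedgehog genes did, from the receptor gene Gas1 (126 ± 9.07) to Shh (2.58 ± 0.332) and Hhip (2.01 ± 0.262); so were all 15 Notch genes (Dll1, 62.0 ± 1.95; Mfng, 54.3 ± 4.52) and all 18 axon guidance genes (Robo3, 98.3 ± 1.12; Nrp1, 87.6 ± 7.18). Of 15 retinoid genes 14 were expressed, with the binding protein genes Crabp1 at 555 ± 65.7 and Crabp2 at 305 ± 16.6 TPM. Of 11 hypoxia and glycolysis genes 10 were (Ldha, 698 ± 42.4), and of 10 immediate early and stress genes 7 (Jun, 83.7 ± 2.36; Fosb, 0.0300 ± 0.0424). All 13 mitochondrial genes (mt-Atp6, 5445 ± 127), all 10 housekeeping genes (Gapdh, 1306 ± 57.2) and all 24 isoform genes passed. In these pools of both sexes Xist stood at 20.96 ± 0.750 TPM, and the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d at 26.9 ± 3.35, 12.1 ± 0.615, 9.88 ± 0.827 and 9.02 ± 0.106 TPM. With a threshold of 5 TPM in both libraries the counts were lower by more than 1.5 times for several lists: 4 ventral progenitor, 6 hedgehog, 4 sensory ganglion, 5 cartilage, 5 epidermal and 4 immediate early genes passed. In the sympathetic, liver, heart and excitatory lists 1 gene each passed, and 0 of the forebrain and midbrain genes, of which 4 passed at 0.5 TPM.

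The 2 libraries were close to each other across genes. Log2(TPM + 1) had a Pearson correlation of 0.985 and a Spearman correlation of 0.986 over 17218 genes, which are not independent replicates, and the biological coefficient of variation was 7.16%. Among the 9835 genes tested at a mean TPM of at least 10, 99.2% lay within 1.5-fold, and 11 differed over 2-fold. The chi-square of the counts was 6.998 per degree of freedom, against counting error alone and with PCR copies counted as reads. Of 20125 genes, 3968 (19.7%) passed the exact binomial test at an adjusted p under 0.05, 2060 higher and 1908 lower in replicate 2, and 687 of these differed over 1.5-fold. These calls compare 2 libraries and have no replicate check. With the common dispersion of all genes included, edgeR's exact test called 238 genes, 92 higher and 146 lower. Scaling by the spike-ins instead gave 3841 higher and 1125 lower, and scaling by TPM 3110 higher and 1425 lower, against a shift of the median of 0.05 and 0.02 on the log2 scale.

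Among well expressed genes, those higher in replicate 2 included Gal, the neuropeptide galanin (12.8 against 22.6 TPM, log2 ratio 0.78), the homeobox gene Hmx1 (7.85 against 14.3 TPM, 0.76) and the phosphatase inhibitor gene Ppp1r1c (34.5 against 58.4 TPM, 0.74). Those lower in replicate 2 included the replication-dependent histone genes Hist1h1b (20.7 against 10.3 TPM, −1.03) and Hist1h2ai (27.2 against 12.8 TPM, −1.10, uncertain because it shares reads with near-identical histone genes), the lincRNA Gm26909 (23.0 against 11.9 TPM, −0.98) and Hoxa11os (27.9 against 14.9 TPM, −0.92), which is antisense to Hoxa11 and whose reads cannot be told from those of the other strand. The most extreme ratios belonged to genes that share reads with copies and are uncertain. Pgk1-rs7, a processed pseudogene at chromosome 12, 10898986 to 10900240, had 484 counts with a posterior SD of 177 in replicate 1 and 8.59 with one of 110 in replicate 2. For mt-Nd4l the counts were 80.2 and 415 with posterior SDs of 132 and 230. The pseudogenes Gm10163, Gm15452, H3f3a-ps2, Gm5537, Gm15899 and Gm4540, the predicted genes Gm4724, Gm20721 and Gm27000, the microRNA gene Gm44330 and the antisense gene Gm44709 also had a posterior SD above 0. Their log2 ratios ran from −1.55 (Gm44330) to 2.58 (Gm5537). Of the 20 named genes, Gm44330, Gm15899 and Gm4540 were no longer called by edgeR's exact test at the common dispersion (adjusted p = 0.190, 0.151 and 0.0957). In the M4 tables the ratio of Pgk1-rs7 was −0.33 instead of −5.55 and that of Gm5537 4.98 instead of 2.58, Gm4540 (0.35) was not called and Gm10163 (0.07) changed direction.

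Sensory ganglion genes had the highest median of any list in replicate 2 relative to replicate 1. All 9 members were higher, with a median log2 ratio of 0.51 (percentile 100 of random lists, whose central 95% ran from −0.11 to 0.12), and 8 passed the exact binomial test, 8 also adjusted over the list alone. The sodium channel gene Scn10a (0.99), the cytoskeletal gene Avil (0.82) and Prdm12 (0.51) were among those that passed, and Calca (0.37) did not pass. Schwann cell and crest genes were also higher, with a median of 0.17, 5 members higher and 1 lower, and the same counts adjusted over the list alone; Gfra3, a GDNF family receptor gene, had a log2 ratio of 0.45 and Ednrb 0.24. Pan-neuronal genes had a median of 0.08, with 10 higher and 1 lower (10 and 1 adjusted over the list alone), Stmn2 at 0.28 and the adhesion gene L1cam at 0.53.

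Motor neuron genes had a median of 0.12 but a mean of −0.02, and their members divided: 6 were higher and 5 lower, 6 and 5 adjusted over the list alone. Prph (0.62), Isl1 (0.42), Isl2 (0.37), Ret (0.22, chosen after its value was seen), Foxp1 (0.13) and Aldh1a2 (0.11) were higher. Lhx4 (−0.72, chosen after its value was seen), Mnx1 (−0.59), Lhx3 (−0.57), Chat (−0.43) and Slc18a3 (−0.17) were lower. Dorsal progenitor genes were higher, with a median of 0.22, 7 higher and 3 lower (7 and 4 adjusted over the list alone). Among them the log2 ratios of Msx1 (0.35), Olig3 (0.27), Msx3 (0.20) and Atoh1 (0.78) were positive. The 3 lower were Pax7 (−0.36) and, chosen after their values were seen, Msx2 (−0.46) and Ptf1a (−0.39). Ventral progenitor genes were lower, with a median of −0.28, 2 higher and 6 lower (3 and 6 adjusted over the list alone). Dbx1 (−0.39), Nkx6-2 (−0.46), Nkx6-1 (−0.28) and Irx3 (−0.21) were lower and Dbx2 (0.51) higher. The sensory ganglion median of 0.51 stands beside these shifts.

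Hox genes were lower in replicate 2, with a median log2 ratio of −0.24 (central 95% of random lists −0.04 to 0.06), 22 lower and 4 higher, and 26 lower and 4 higher adjusted over the list alone. The 4 higher were Hoxa7 (0.26), Hoxa9 (0.13), Hoxc6 (0.18) and Hoxc8 (0.52). By paralog group, the median was between −0.23 and −0.35 in groups 1 to 5, between −0.04 and 0.15 in groups 6 to 9, −0.11 in group 10, −0.42 in group 11, −0.92 in group 12 and −2.43 in group 13. Hoxb13 (ENSMUSG00000049604.3, chromosome 11, 96194316 to 96197447, mm10) had 263 counts in replicate 1 and 38 in replicate 2, a log2 ratio of −2.81 (exact binomial test, Benjamini-Hochberg adjusted p = 5.29e-43). Hoxa13, Hoxd13 and Hoxc13 had log2 ratios of −3.19, −2.06 and −1.46.

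Skeletal muscle genes were lower beside them: all 12 members passed the test, 12 also adjusted over the list alone, with a median of −0.51. Actc1 (−0.60), Acta1 (−0.50), Myog (−0.36) and the myogenic factor gene Myf5 (−1.09) were among them. Liver genes had a median of −0.78 (3 lower, 4 adjusted over the list alone) and heart genes −0.66 (4 lower, 5 adjusted over the list alone). Levels were low, such as 4.68 and 0.63 TPM for the myosin light chain gene Myl2. With log2 ratios of TPM + 1 the medians were −0.39 for liver and −0.50 for heart genes, and both calls held. Whether heart genes marked heart tissue or skeletal muscle was not tested. Cartilage and sclerotome genes had a median of −0.17 (1 higher and 5 lower, or 2 and 5 adjusted over the list alone). Their call ended with log2 ratios of TPM + 1 (−0.09), where scale and pseudocount both changed. Sympathetic genes had a median of −0.47 with 1 higher (Th, 0.34) and 1 lower, the same adjusted over the list alone. That call ended with spike-in scaling (−0.42) and with log2 ratios of TPM + 1 (−0.19), where scale and pseudocount both changed. Mesenchyme and meninges genes (−0.08; 1 higher and 2 lower, 3 and 5 adjusted over the list alone) sat at the edge of the random lists, and the call ended with DESeq2 size factors.

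Smaller shifts downward were called for inhibitory transmitter genes (median −0.17; 2 lower, 4 adjusted over the list alone), among them Gad2 (−0.17) and Gad1 (−0.19). Retinoid genes had a median of −0.12, with 2 higher and 5 lower, 2 and 5 adjusted over the list alone, among them Crabp1 (−0.28). Dorsal interneuron genes had a median of −0.09, with 3 higher (Pou4f1 at 0.26, Tlx3 at 0.34 and Prrxl1 at 0.32) and 4 lower, 3 and 6 adjusted over the list alone. Their call ended with log2 ratios of TPM + 1 (−0.04), where scale and pseudocount both changed. Proliferation genes had a median of −0.05, with 8 lower and 0 higher, 8 and 0 adjusted over the list alone. With spike-in scaling, which moves all genes up alike, the median was 0.0041 and the call held. The call ended with log2 ratios of TPM + 1 (−0.0046).

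The other 20 lists lay inside the central 95%. Their medians were −0.04 for neural progenitor, 0.07 for commitment to the neuronal fate, −0.12 for ventral interneuron, −0.03 for glial, 0.15 for excitatory, −0.15 for monoamine and 0.40 for forebrain and midbrain genes. For hedgehog, Notch, axon guidance, erythroid and endothelial genes they were 0.07, −0.01, −0.03, −0.05 and 0.06. They were 0.05 for pericyte, 0.10 for macrophage and microglia, −0.02 for epidermal and epithelial, 0.04 for sex-linked and −0.01 for mitochondrial genes. Immediate early, hypoxia and housekeeping genes had −0.04, −0.02 and −0.03. With log2 ratios of TPM + 1, where scale and pseudocount both changed, the medians were 0.05 for monoamine, −0.04 for hedgehog and 0.08 for forebrain and midbrain genes. The monoamine median was 0.16 with at least 100 counts. Other medians near 0 also changed sign with spike-in scaling or TPM, and under both scalings all 20 lists stayed inside. In hedgehog, Notch, pericyte, epidermal and mitochondrial genes the mean had the opposite sign to the median (−0.01, 0.01, −0.02, 0.02 and 0.12). The members that passed the test, given as higher and lower, were 3 and 2 of the neural progenitor genes (3 and 3 adjusted over the list alone), 0 and 3 of the ventral interneuron genes (0 and 4) and 2 and 2 of the glial genes (3 and 2). They were 2 and 0 for hedgehog (2 and 1 adjusted over the list alone), 6 and 5 for axon guidance (6 and 6), 0 and 1 for pericyte (1 and 2), 3 and 5 for mitochondrial (4 and 5) and 1 and 5 for housekeeping genes (2 and 6). For the rest the counts were the same adjusted over the list alone: 4 and 2 for commitment to the neuronal fate, 3 and 2 for Notch, 1 and 5 for erythroid, 4 and 0 for endothelial, 1 and 1 for sex-linked, 1 and 2 for hypoxia and 0 and 1 for immediate early genes. Monoamine (Th) and forebrain and midbrain genes (Emx2, log2 ratio 1.87) had 1 and 0, and excitatory, macrophage and epidermal genes 0 and 0. In all, 17 of 37 lists lay outside, 5 higher and 12 lower, where lists of genes drawn independently would give 1.85. Members of a list can vary together and some lists share genes, so 1.85 does not measure chance for these lists.

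**Figure D3:**
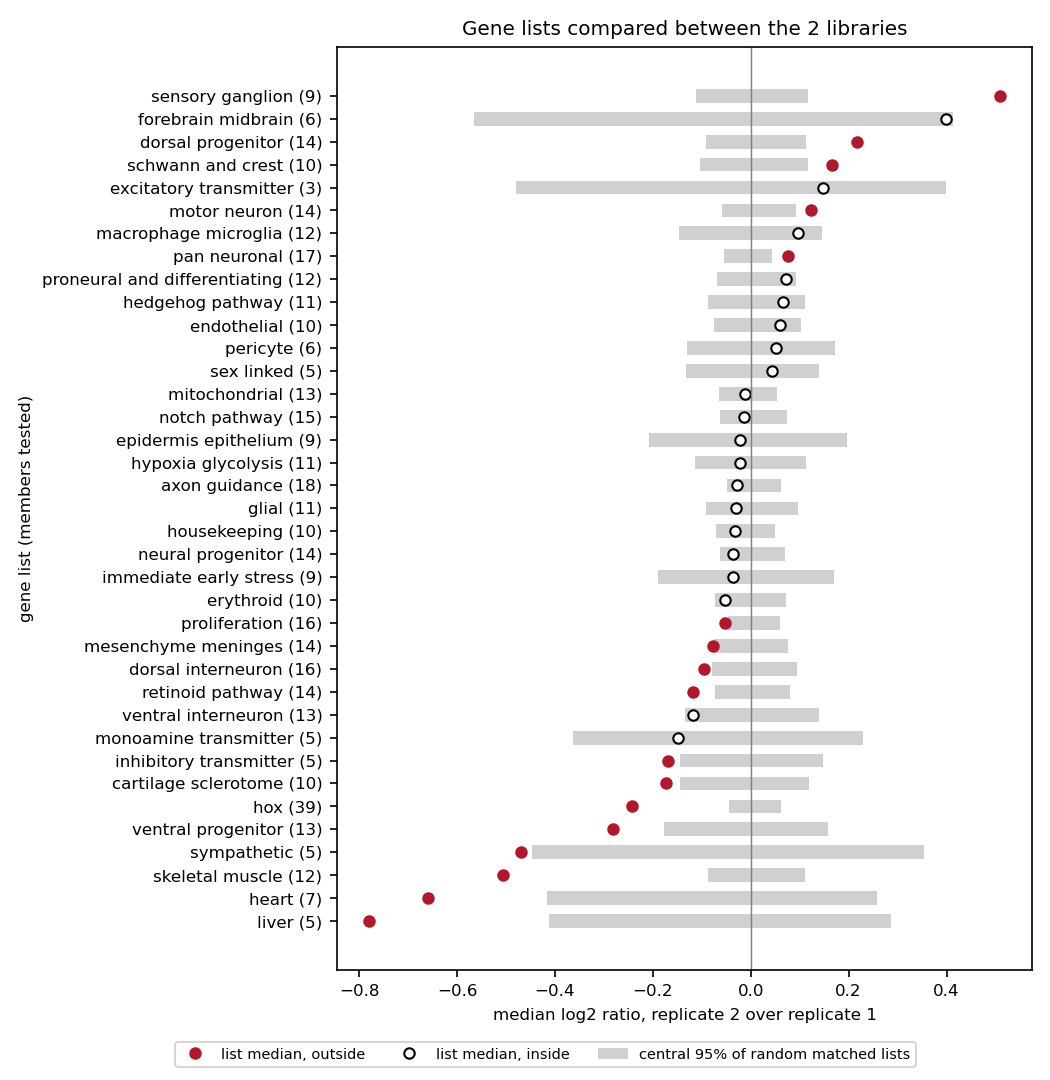
Median log2 ratio of replicate 2 over replicate 1 for 37 gene lists (number of members tested in parentheses); grey bars are the central 95% of 10000 random lists matched on expression, red points lie outside and open points inside. Sensory ganglion genes (0.51) lie farthest to the right, and liver (−0.78), heart (−0.66) and skeletal muscle genes (−0.51) farthest to the left.

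The transcript tables showed which forms of neuronal genes were present. Of 8720 genes with several annotated transcripts at a TPM of at least 10, 93.2% had the same leading transcript in both libraries, and its median share was 66.0% ± 0.438. Of the 24 isoform genes, Snap25 and Kif5a, for synaptic fusion and axonal transport, were dominated by Snap25-201 (91.8% ± 0.820) and Kif5a-201 (91.6% ± 0.509), and Tpm3 by Tpm3-201 (83.1% ± 1.03). Cdc42-202 held 74.9% ± 0.912, Pkm-201 68.6% ± 0.438, Ptbp2-201 66.1% ± 2.41 and Ncam1-204 63.3% ± 0.148. The splicing factor gene Rbfox2 had Rbfox2-203 at 59.1% ± 1.74, and its relative Rbfox1 had Rbfox1-207 and Rbfox1-202 at 37.1% ± 6.59 and 32.5% ± 8.69, a difference within the spread between libraries. The leading transcript of Agrn was Agrn-205, annotated as a retained intron, at 49.2% ± 0.884. For the microtubule proteins, Map2-201 held 41.9% ± 3.30, Mapt-205 48.7% ± 1.55 and Dcx-203 46.5% ± 1.75. The other 11 included Ank3, Camk2b, Clta, Cltb, Dlg4, Dnm1, Nfasc, Nrcam, Numb and Tpm1, with leading shares from 20.7% (Ank3-231) to 54.9% (Cltb-201).

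The same reads quantified against the M21 and M4 annotations gave close levels, with a Spearman correlation of 0.993 in each library across 42462 shared genes. Over the 15753 genes at a TPM of at least 1 it was 0.9815 in replicate 1 and 0.9822 in replicate 2. In both libraries 381 genes differed over 2-fold in TPM + 1, 240 higher and 141 lower with M21. Among 450 listed genes, Nrcam, a neuronal adhesion gene (89.3 against 38.2 TPM), and Dbx2 (5.58 against 2.15 TPM) did. The protein-coding genes Usp50 (2.60 TPM with M21 and 217 with M4), Ptp4a1 (3.79 and 266) and Nupl1 (0 and 0.02 in the 2 libraries with M21, and a mean of 43.8 with M4) differed most among coding genes, before Gm49342 and Pagr1b, at 0 with M21 and 32.2 and 31.9 with M4. Pseudogenes and the lincRNA Gm7292 also differed, the pseudogenes in both directions, such as Gm6565 (0 and 105) and Gm6361 (102 and 0). Gm10774 and Gm5616 were at 75.6 and 61.9 TPM with M21. Whether reads moved between particular genes was not tested. The ERCC spike-ins took 2.99% of counts in replicate 1 (95% Wilson interval 2.98 to 2.99) and 2.89% in replicate 2 (2.88 to 2.90). Of 96 spike-ins 87 and 82 were detected.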

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

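Transfer RNA genes, which no comparison uses, held some reads. The deposited tables have 26248 such entries, of which 8 had reads in each library. They summed to 37.6 estimated counts in replicate 1 and 31.6 in replicate 2, above the 3 counts that a total of 0 allows. There is no control library to set them against, and no explanation was tested. With 2 libraries in a single group, outlying samples and differences between groups were not testable.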

How the results depend on the processing

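All but the length and GC trend and 1 alternative not reported here were fixed before the data were examined. No paired analysis was possible because there is only 1 group. Among the list medians, proliferation lay at 0.0041 with spike-in scaling, which moves all genes up alike and left the list below the central 95% of random lists. With log2 ratios of TPM + 1, proliferation (−0.0046), dorsal interneuron (−0.0420), sympathetic (−0.19) and cartilage genes (−0.0887) were no longer called. That alternative changed the pseudocount together with the scale. Sympathetic genes also lost their call with spike-in scaling (−0.42), and mesenchyme genes with DESeq2 size factors (−0.0762). With at least 100 counts 5 lists had too few members for a value. Removing the length and GC trend left the call of 36 of 37 lists as it was and added axon guidance (−0.05). The number of genes that differed between the libraries fell to 238 with edgeR's exact test, whose construction adds the spread of all genes to counting error. Gm10163 was at 0.0725, the opposite direction, in the M4 tables, and 2 of the 20 named genes were not in those tables.

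The contrasts without length correction were 4.22 (Slc17a6 over Slc32a1), 4.51 (Tubb3 over Sox2), 2.36 (Pax3 over Nkx6-1), 1.45 (Hox 5 to 8 over 1 to 4) and 1.965 (Hox 9 over 1 to 4), and Tubb3 over Sox2 was 4.73 with M4. Pearson's correlation between the libraries was 0.953 with a pseudocount of 0.1, 0.992 over all genes with a count, 0.988 at a TPM of 10 and 0.986 with M4. The same leading transcript was found for 90.1% of genes at a TPM of at least 1. At 1.5-fold, 876 genes differed between the annotations, and spike-ins took 3.02% of counts with M4. Unless stated, the cause was not tested. Of the values of main results under these alternatives, 159 kept their direction and call or, where there is no call, stayed within 1.5-fold or their spread; 14 moved, 6 lost their call and 1, the proliferation median above, changed sign. Depth limits the Hox group 13, heart, liver and sympathetic genes, several of which had under 100 counts.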

Other observations

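The sets of neuropeptide, imprinted and histone genes were chosen after the data were seen, and so were the tests on interneuron lists, the length and GC trend, the endothelial list, the common dispersion, the summed histone counts and the other RNAs without a tail. The tests on new sensory neuron, tail-level and S phase genes were fixed before their values were seen.

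Several neuropeptide genes were already active. Npy stood at 173 TPM and Sst at 110 TPM, followed by Tac1 (22.3), Penk (17.8), Gal (17.7), Adcyap1 (16.6) and Pdyn (7.66), while Cck, Nts and Vip were at 0.940, 0.490 and 0.390 TPM. Among imprinted genes looked up, beside Nnat at 2621 TPM, the cell cycle inhibitor Cdkn1c reached 1046 TPM, Meg3 867, Mest 611, Grb10 258, Snrpn 254, Igf2 225, Ndn 187 and H19 161 TPM. Among genes annotated as lincRNA, Malat1 (7145 TPM) and Gm26917 (3623 TPM) had the highest levels. Whether the reads of Gm26917 came from a lincRNA or from another RNA of that locus was not tested. Hosts of neural microRNAs lay further down (Mir9-3hg at 98.2 and Mir124-2hg at 89.4 TPM). Of pyruvate kinase transcripts with either exon of the mutually exclusive pair, those with the upstream exon (chromosome 9, 59675029 to 59675195, mm10) held 30.02% ± 0.336 (SD, n = 2) and those with the downstream exon (59675568 to 59675734) 69.98% ± 0.336. By textbook knowledge the upstream exon marks the form of mature muscle and brain and the downstream exon that of proliferating cells.

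Sensory ganglion genes were higher in replicate 2, with a median log2 ratio of 0.51. A general excess of neurons of every class is argued against as the whole cause by the dorsal (−0.09) and ventral (−0.12) interneuron medians. Both had been seen before the lists were pooled, so the pooled median of −0.10 is not a separate test. However, pan-neuronal genes were higher (0.08). The interneuron lists mark neuron classes rather than maturity, so a more mature pool was not tested. A length or GC trend is argued against by the median of 0.51 that stayed after its removal. More ganglion tissue in that pool may account for it: a second set of 8 sensory neuron genes fixed beforehand had a median of 0.61 (central 95% of random lists −0.18 to 0.17), with 6 genes higher (5 called) and 2 lower (1 called). Eya2 (0.62), Tlx2 (0.61) and Trpv1 (1.67, from 14 and 52 counts) were among the higher ones. Of the 9 sensory ganglion genes, 0 are in another of the lists fixed beforehand, though Prdm12 and Calca are also known from the cord itself; the labels name no sort, and how each pool was dissected is not given in the sources used here.

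Hox genes of groups 12 and 13 were lower in replicate 2, with group medians of −0.92 and −2.43. Counting noise alone is argued against for these 6 genes, all called by the exact binomial test, which covers counting error only. EdgeR's exact test, at a common dispersion taken from the same 2 libraries, called all 6 too. Of the 6 genes of groups 10 and 11 the exact binomial test called 4 and edgeR's test 0. The groups were divided there after these outcomes were seen, so the contrast between them is no support. A lower share of neural tissue in replicate 1 could not be decided. The endothelial median lay 0.57 above that of skeletal muscle, and macrophage genes (0.10) were not lower either. However, other tissues need not move alike, and how far endothelial and macrophage genes came from within the cord was not measured. Mesenchyme (−0.08), cartilage (−0.17), liver (−0.78) and heart genes (−0.66) were lower. More tissue of tail or hindlimb level in the replicate 1 pool may account for groups 12 and 13. Of 14 tail bud and hindlimb-level genes fixed beforehand 7 had enough counts, with a median of −0.44 (central 95% −0.36 to 0.26). All 7 were lower and 2 were called, Pitx1 (−1.93) and Wnt5b (−0.44). Tbx4 (−0.64), T (−0.50), Nkx1-2 (−0.19), Tbx6 (−0.08) and Gdf11 (−0.01) were not called. The set mixes both kinds of gene, so it cannot tell tail from hindlimb tissue. An excess of either leaves open why groups 1 to 5 (medians −0.23 to −0.35) lay below group 10 (−0.11), and why skeletal muscle genes were lower too.

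Replication-dependent histone genes were lower in replicate 2, with a median log2 ratio of −0.42 over 58 genes, a set chosen after 2 of its members had been seen to be lower, 21 called lower and 2 higher. Fewer cells in S phase is argued against as the whole cause by 20 S phase genes fixed beforehand, with a median of −0.0334. However, 15 of the 20 were lower and the proliferation list was too (−0.05). Reads moved only among the 58 genes are argued against by their summed counts, at −0.29, and at −0.42 without Hist1h2ap. Whether reads moved to copies outside this set was not tested. Less priming of RNA without a poly(A) tail could not be decided: 5 other such RNAs had a median of −0.33, but they differed in direction. Malat1 (−0.46), Rn7sk (−0.34) and Rpph1 (−0.33) were lower, while Rn7s1 with Rn7s2 was at 0.02 and Rmrp, with few counts, at 0.74. The labels name 1 group, so a biological difference between groups was not tested as an explanation.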
